A study of Caenorhabditis elegans with 2 samples.

How the data were processed

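Chromatin of whole worms was sheared by sonication and precipitated with an antibody against the green fluorescent protein in 2 biological replicates, per the labels. The replicates came from separate biosamples. The deposited files were peak lists on builds ce10 and ce11: a relaxed list for each replicate, which holds peaks and background meant as input for a reproducibility analysis, a relaxed list from pooled replicates, and a thresholded optimal list. The reproducibility analysis compares the ranks of peaks in replicates (irreproducible discovery rate, IDR), per the titles the authors gave the lists. The signal of each peak was computed by the authors' peak caller and used as deposited. It was used to describe and rank peaks within a list and, between the replicates, in correlations, which a difference of scale leaves as they are; its scale differs between lists. The −log10 of the q-value was also deposited by the authors. It held the single value 2.18 throughout the optimal list and was not used as a filter. The aligner, the peak caller, its thresholds and the treatment of the control are not given in the sources used here. The control library was not analysed here.

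The files hold no read counts, so the depth of each library is unknown, and intervals on shares of peaks cover counting error only. Most regions of a list shared its median width (325 of the 412 optimal peaks, at 420 bp), so positions were compared by summit. The 412 optimal peaks formed 394 distinct regions, since 24 mitochondrial summits lay in 6 regions. Every step with genes or sequence used build ce11, which equals the reference genome used here (WBcel235, annotation release 115 of Ensembl), and all peaks lay within its chromosome lengths. The ce10 lists were used only for counts of peaks, also by chromosome, and for agreement and correlation of the replicates. Circular shifts of the ce10 lists used the chromosome lengths of ce11. No coordinate was converted.

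Relaxed-only peaks were the 9995 pooled relaxed peaks that overlapped no optimal peak. They served as background for promoters, feature classes and chromosomes, with Fisher's exact test, two-sided. Sharing was defined by summits within 100 bp and tested with 1000 seeded circular shifts of replicate 1 along each chromosome. Correlations used mutually nearest summits within 100 bp. The promoter window ran from 1000 bp upstream to 500 bp downstream of any protein-coding transcript start, and a summit was placed in the first fitting class of promoter, 5′ untranslated region, coding sequence, 3′ untranslated region, intron, noncoding gene and intergenic sequence. Gene lists were tested with Fisher's exact test over 19973 protein-coding genes of the nuclear chromosomes, and symbol prefixes were tested when they had at least 10 genes. Odds ratios had 0.5 added to each cell. Hexamers on either strand were compared by the exact McNemar test between the window of 50 bp on each side of the summit and a window of equal width 400 bp away on a seeded side. Adjusted p-values are from the Benjamini-Hochberg method, with a threshold of 0.05. Intervals on shares are Wilson intervals at the 95% level. Where a count was 0, the upper limit given is instead 3 counts of the total.

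Peaks with several nearby genes link to each of them, so linked genes are not fully independent. In the gene lists, 10 symbols had no match in the annotation and were left out. Lists defined by a prefix took only symbols in which a number follows the prefix, so rpl-7A was missed. The histone list held 52 genes, while the prefix his alone had 72. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. On simulated data, a planted list with 19% linked genes among 20000 was recovered in 100% of 100 runs with 0.0952% of other lists called. The planted list was about as strong as the ribosomal protein list in these data, and genes were linked independently. These runs therefore do not show the power for smaller or weaker lists. A hexamer planted in 20% of windows was recovered in 100% of 20 runs, and a planted sharing of 15% was estimated at 14.7%. The simulated windows had the same base composition at summits and flanks, unlike these data.

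Groups, tests, gene lists, hexamers, the rule for named genes and the other settings to be tried were fixed before the data were examined. The rule named ceh-32, the nearest protein-coding gene of the 25 optimal peaks with the highest signal, the 4 linked members with the strongest peaks in each list past the threshold, and linked sine oculis, PAX and EYA genes. Because 23 of those 25 peaks were mitochondrial, and many genes there have no symbol in the annotation, the mitochondrial peaks are given as a group. The strongest nuclear peaks, linked members of lists that did not pass, members of symbol classes and hexamers outside the 4 fixed ones were named after their values were seen. The other settings were other distances and overlap rules for sharing, other promoter windows, nearest-gene linking within 5 kb, a permutation of 10000 draws matched on upstream intergenic length in 10 bins, a background of genes with a relaxed peak, other hexamer windows and controls, the 206 strongest optimal peaks, the ce10 lists and the list of each replicate alone. For the last, the 412 strongest peaks of 1 replicate replaced the optimal list. Leaving out the mitochondrial peaks, leaving out the peaks near ceh-32, and splitting promoters by autosomes and X, with the difference of their log2 odds ratios, were added after the data were examined.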

Results

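Binding of CEH-32, a homeodomain transcription factor of the sine oculis family, was profiled by chromatin immunoprecipitation and sequencing in the nematode Caenorhabditis elegans. The worms were whole hermaphrodites at the fourth larval stage, collected 52 hours after release from starvation-synchronised first-stage larvae. They carried a transgene that expresses CEH-32 fused to a green fluorescent protein and FLAG tag, in a strain with a mutation of unc-119, the gene used to select transformed animals. Chromatin was precipitated with an antibody against the fluorescent protein. There was 1 group of 2 replicates from separate worm preparations, so no comparison between conditions was possible. The data were peak lists in which each peak had the signal that the authors' peak caller gave it. The number of reads behind each list was not used here, so the depth is unknown. The design asks where the tagged protein was found reproducibly, near which genes and over which sequences.

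The authors' list of reproducible peaks, called optimal peaks here, held 412 peaks on build ce11. Of these, 388 lay on the 6 nuclear chromosomes and 24 on the mitochondrial genome. Signal ranged from 81.6 to 435 over the nuclear peaks and from 407 to 21821 over the mitochondrial ones. The 23 strongest peaks were all mitochondrial. The strongest nuclear peak lay at III, 3867447 to 3867715, with its summit 271 bp upstream of the start of rpl-3 (WBGene00004414), which encodes a protein of the large ribosomal subunit. Its signal was 435 in the pooled list, 196 in replicate 1 and 238 in replicate 2. The next nuclear peak lay between genes at X, 4209131 to 4209439, 1798 bp upstream of F20B6.9 (WBGene00017632), with a signal of 413. The optimal list was identical to the 412 strongest of the 10485 relaxed peaks called on the pooled reads. The relaxed lists held 14069 peaks for replicate 1 and 14710 for replicate 2.

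The relaxed lists of the replicates shared more peaks than shifted positions did, though most of their peaks were not shared. The optimal list was selected by the authors for reproducibility and equals the strongest peaks of the same pooled replicates, so its recurrence in each replicate follows from that selection. Of the 412 optimal peaks, 96.6% had a summit within 100 bp in the relaxed list of replicate 1 (Wilson 95% interval 94.4% to 98.0%) and 94.7% in that of replicate 2 (92.0% to 96.4%). Among all relaxed peaks of replicate 1, 17.9% were shared with replicate 2, against 3.04% ± 0.15 (SD, 1000 circular shifts) when positions were shifted along each chromosome. The two-sided permutation p was 0.0020, the smallest that these shifts can give. Sharing was concentrated at the top of the lists. It reached 91% for the 100 strongest peaks of replicate 1 and 94% for the 100 strongest of replicate 2, and was 30.6% and 29.7% for the 5000 strongest. Among the 412 strongest peaks of each replicate, 303 and 305 of the optimal peaks were found, and 212 were found in both.

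Signal at matched peaks was related across the replicates. Over 2512 matched peaks, which are not independent replicates, Spearman's rho was 0.533 and Pearson's r 0.959. Pearson's r was 0.806 and rho 0.521 over the 2491 nuclear matches alone, a comparison chosen after the data were examined. Over the optimal nuclear peaks found in both replicates, rho was 0.372 (n = 356), with 0.484 on the X chromosome (n = 114) and 0.315 on the autosomes (n = 242). The optimal peaks are those with the highest pooled signal, and a cut on pooled signal can by itself lower rho. The lower values are therefore no sign of poorer agreement at these peaks.

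**Figure D1:**
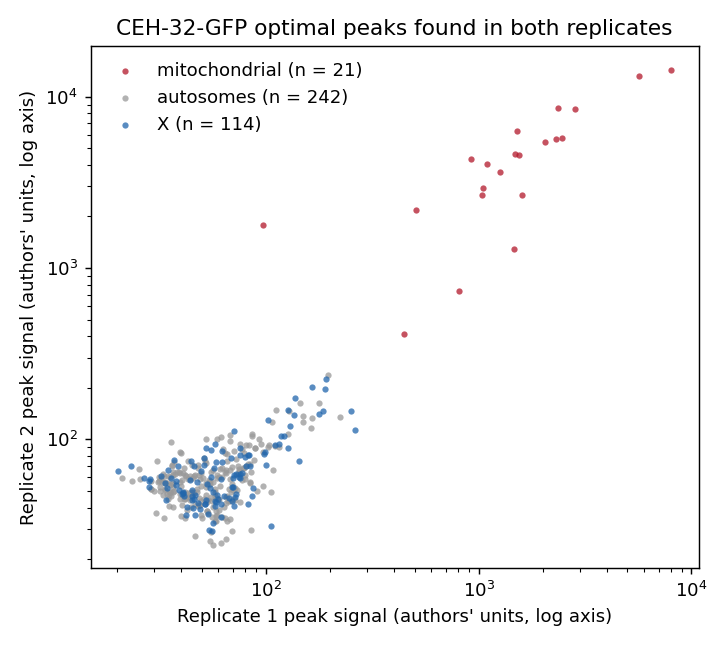
Signal of each optimal peak in replicate 1 (x axis) and replicate 2 (y axis), in the authors' units on log axes, for the peaks found in both replicates. Each point is a peak, coloured by mitochondrial genome, autosome or X chromosome; the 21 mitochondrial peaks lie mostly far above the 356 nuclear ones.

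Peaks on the X chromosome were over-represented among the optimal peaks. X held 122 of the 388 nuclear optimal peaks, or 31.4% (Wilson 95% interval 27.0% to 36.2%), against 20.1% of the pooled relaxed peaks that overlapped no optimal peak, called relaxed-only here. The log2 odds ratio was 0.87 ± 0.16 (SE; Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over 6 chromosomes, p = 1.5e-06). Chromosome IV held fewer than its share, 11.3% against 17.6% (log2 odds ratio -0.73 ± 0.23, adjusted exact p = 0.0030). Chromosomes I, II, III and V did not differ from the relaxed peaks, with adjusted exact p from 0.585 to 0.941. The density was 6.89 optimal peaks per Mb on X and between 2.52 and 3.99 on the autosomes. X took 39.2% of the 97 strongest nuclear optimal peaks (38 peaks; Wilson 95% interval 30.1% to 49.1%) and 26.8% of the 97 weakest (26 peaks; 19.0% to 36.4%), intervals that overlap. Against chromosome length in place of relaxed peaks, chromosome V was also low, with 14.2% of peaks on 20.9% of the sequence (exact binomial test, adjusted p = 0.0020).

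Among the 25 strongest nuclear peaks, a set chosen after the data were examined, 12 were on X. Only 2 of those 12 had their summit in a promoter window. Examples between genes on X were the peak at 11093986 to 11094361 (signal 391; 253 in replicate 1 and 146 in replicate 2), the peak at 9465709 to 9465991 (signal 377; 191 and 196) and the peak at 13700694 to 13701005 (signal 363; 165 and 201). A peak of signal 301 at X, 8036301 to 8036576, was 4900 bp upstream of xol-1, the switch gene of sex determination and dosage compensation. Autosomal examples were the promoter peaks of egg-5 (signal 305), with a summit 596 bp from the start of egg-5 and 21 bp from the spliced leader RNA gene sls-2.4, and of tasp-1 (signal 299).

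**Figure D2:**
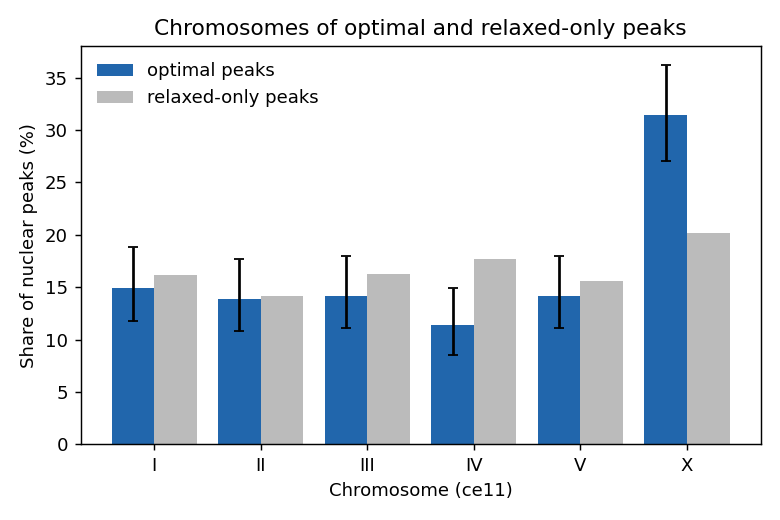
Share of nuclear peaks on each chromosome (y axis, percent) for the 388 optimal peaks (blue, with Wilson 95% intervals) and for the 9995 relaxed-only peaks (grey). X holds 31.4% of the optimal and 20.1% of the relaxed-only peaks.

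Promoters were over-represented at the optimal peaks, and this held on the autosomes but was not detected on X. Of all 412 optimal peaks, 57.3% had their summit between 1000 bp upstream and 500 bp downstream of a protein-coding transcript start (Wilson 95% interval 52.5% to 62.0%), against 38.7% of relaxed-only peaks (log2 odds ratio 1.09 ± 0.15 SE; Fisher's exact test, two-sided, p = 1.0e-13). The 412 include 24 mitochondrial peaks, while the relaxed-only peaks were all nuclear. Over the nuclear peaks alone, a setting chosen after the data were examined, the share was 55.4% (log2 odds ratio 0.98 ± 0.15 SE, exact p = 7.3e-11). Circular shifts of the nuclear peaks gave 30.8% ± 2.38 (SD). On the autosomes 63.9% of 266 optimal peaks were in promoters, against 40.4% of relaxed-only peaks (exact p = 4.7e-14). On X it was 36.9% of 122, against 31.9% (exact p = 0.272). The share on X was lower than that on the autosomes (log2 odds ratio -1.59 ± 0.33 SE, exact p = 1.1e-06, a test chosen after the data were examined). The log2 odds ratio against relaxed-only peaks was 0.33 ± 0.28 (SE) on X and 1.38 ± 0.19 on the autosomes, a difference of -1.05 with a 95% interval from -1.71 to -0.40, also computed after the data were examined. Intergenic sequence instead held 38.5% of the X-linked and 13.2% of the autosomal optimal peaks.

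Coding sequence and 3′ untranslated regions were depleted. Coding exons outside promoter windows held 2 of the 388 nuclear optimal peaks, or 0.515%, against 13.4% of relaxed-only peaks (log2 odds ratio -4.58, adjusted exact p = 3.6e-20 over 7 classes). No optimal peak had its summit in a 3′ untranslated region outside promoter windows (0 of 388, which allows a share of up to 0.773%), against 3.61% of relaxed-only peaks (adjusted exact p = 3.4e-06). Noncoding genes outside promoter windows held 4.64% against 2.30% (adjusted exact p = 0.011). Introns held 18.04% against 22.03% (adjusted exact p = 0.097), and intergenic sequence 21.1% against 19.6% (adjusted exact p = 0.553).

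Genes of protein synthesis and folding stood out among the linked genes. A gene was linked when an optimal summit fell in its promoter window, which gave 281 of the 19973 nuclear protein-coding genes, or 1.41%. Of 79 ribosomal protein genes, 15 were linked, or 19.0%, against 1.34% of other genes (log2 odds ratio 4.15 ± 0.42 SE; Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over 22 lists, p = 6.1e-12). Among these the peaks were strongest at rpl-3, rpl-15 (signal 284), rpl-20 (270) and rpl-35 (196), all of the large subunit. The gene rpl-7A, also linked (signal 85.4), was not in this list because its symbol ends in a letter, and it counted among the other genes. Of 43 translation factor and core chaperone genes, 11 were linked, or 25.6% (log2 odds ratio 4.68 ± 0.50 SE, adjusted exact p = 1.5e-10). The strongest were at hsp-60 (signal 170), the mitochondrial chaperonin, eif-3.C (164), a subunit of an initiation factor, cct-8 (161), a subunit of the cytosolic chaperonin, and hsp-90 (153). The 15 and 11 genes of these lists were linked through as many distinct peaks, but 6 and 4 of these peaks were nearer the start of another gene. Among the genes named, these were rpl-20 (319 bp from the summit, Y17G9B.5 at 143 bp), hsp-60 (621 bp, Y22D7AL.10 at 192 bp), cct-8 (432 bp, Y55F3AR.2 at 189 bp) and hsp-90 (400 bp, C47E8.4 at 275 bp). With each peak linked to the nearest start within 5 kb, 9 of 79 and 7 of 43 were linked (adjusted exact p = 8.4e-05 for both).

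Of 22 molting and heterochronic regulators, 3 were linked (log2 odds ratio 3.66 ± 0.84 SE, adjusted exact p = 0.019). These were lin-66, with a peak signal of 160, ain-1, a partner of the microRNA machinery, with 135, and myrf-1, a membrane-bound transcription factor, with 93.6. The ain-1 peak had a signal of 106 in replicate 1 and 31.4 in replicate 2. This call rests on 3 genes and was lost in 5 of 9 alternatives. In 4 of these 2 genes were linked and the log2 odds ratio stayed high: 3.13 ± 0.97 (SE) with the list of replicate 2 alone (adjusted exact p = 0.133), 3.09 ± 0.97 with that of replicate 1 alone (adjusted exact p = 0.169), 4.20 ± 0.97 over the 206 strongest peaks (adjusted exact p = 0.051) and 3.60 ± 0.97 with promoters from 500 bp upstream (adjusted exact p = 0.074). Against genes with a relaxed peak it was 2.46 ± 0.92 (adjusted exact p = 0.268).

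Chemoreceptor genes were linked less often than other genes. Of 1300, 3 were linked, or 0.231% against 1.49% (log2 odds ratio -2.49 ± 0.78 SE, adjusted exact p = 1.0e-04). The 3 were sre-23 (signal 114), srh-16 (92.7) and sri-5 (82.1). Against the 4005 genes with a relaxed peak in their promoter window the depletion was not detected (log2 odds ratio -0.87 ± 0.79 SE, adjusted exact p = 0.666).

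Apart from the 4 lists above, no list of developmental regulators or tissue genes passed the test with the optimal list and promoter windows. Of 15 sine oculis, PAX and EYA genes, which include relatives and partners of CEH-32, 1 was linked, ceh-32 itself (adjusted exact p = 0.422). Of 96 homeobox genes 3 were linked, ceh-32, ceh-38 (signal 88.0) and unc-42 (86.3) (adjusted exact p = 0.421). The list of 15 inducible heat shock genes had 2 linked members, hsp-110 and dnj-13 (adjusted exact p = 0.081), and the 52 histone genes had 3, his-37, his-67 and his-68, through 2 peaks (adjusted exact p = 0.135). Of 42 pan-neuronal genes 2 were linked, maco-1 and unc-108 (adjusted exact p = 0.370), but 5 with the list of replicate 2 alone, which passed (log2 odds ratio 3.41 ± 0.66 SE, adjusted exact p = 0.0015), and the Wnt, Notch, TGF-beta and EGF signalling list had 2 of 63, mig-5 and egl-17 (adjusted exact p = 0.444), but 6 when linked by the nearest start within 5 kb (log2 odds ratio 2.73 ± 0.60 SE, adjusted exact p = 0.0034). The gene egl-17 also was the 1 linked member of 36 somatic gonad and vulva genes (adjusted exact p = 0.733). The other lists with 1 linked gene were nuclear hormone receptors (nhr-40, 1 of 269, adjusted exact p = 0.422), basic helix-loop-helix genes (mdl-1, 1 of 40, adjusted exact p = 0.733), cuticle collagens (col-85, 1 of 176, adjusted exact p = 0.770), hypodermis and hedgehog-related genes (wrt-3, 1 of 109, adjusted exact p = 1), body wall muscle genes (act-4, 1 of 49, adjusted exact p = 0.770) and neuropeptide genes (ins-39, 1 of 146, adjusted exact p = 0.940). The lists of pharynx, intestine, germline, neurotransmitter pathway and axon guidance genes had no linked member of 43, 74, 54, 36 and 45, with adjusted exact p from 0.865 to 1. Some of the summits linked to list members were also at small noncoding RNA genes: those of egl-17 and col-85 were inside transfer RNA genes, and those of sre-23, wrt-3 and rps-26 were 58, 64 and 95 bp from small nucleolar RNA genes. With 0.506 to 1.04 linked genes expected in each of the 5 lists without a linked member, a lower share was not detectable.

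**Figure D3:**
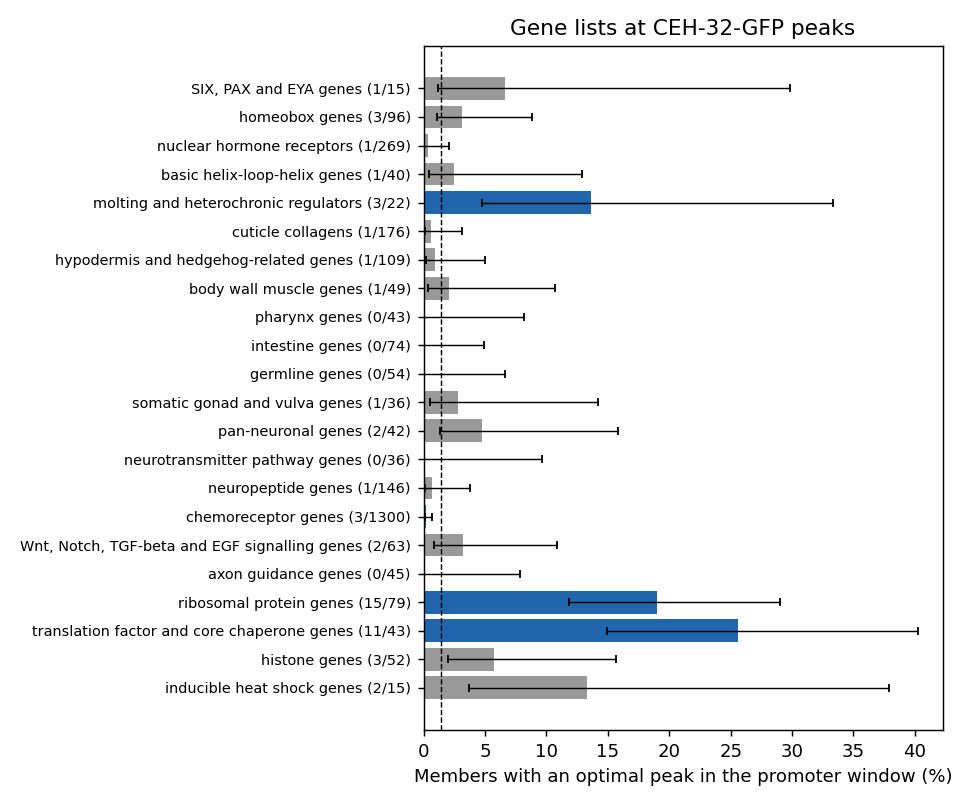
Members of each gene list with an optimal peak in the promoter window (x axis, percent, with Wilson 95% intervals; linked and total members in parentheses). Blue bars passed the adjusted threshold, as did chemoreceptor genes, whose bar of 0.231% is too short to see; the dashed line marks the 1.41% of all tested genes.

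Genes grouped by the prefix of their symbol gave 4 classes past the threshold among 175 tested. These were rpl (9 of 47, adjusted p = 2.8e-06), rps (7 of 31, adjusted p = 1.7e-05), hsp (5 of 22, adjusted p = 6.7e-04) and lin (5 of 47, adjusted p = 0.022; Fisher's exact test with Benjamini-Hochberg adjustment). The hsp members were hsp-60, hsp-90, hsp-3, hsp-110 and hsp-1. All but hsp-110 are also in the translation factor and core chaperone list, so this class is not separate from it. The peaks of hsp-60 and hsp-90 were nearer another gene, as given above. That of hsp-110 was 237 bp from its start and 207 bp from that of rpn-3. The lin genes share only a mutant phenotype class, and the 5 were lin-66, lin-9, lin-53, lin-54 and lin-59, of which lin-9, lin-53 and lin-54 encode subunits of the DREAM repressor complex. The peak at lin-54 was also the promoter peak of rpl-12. The hsp class was lost in 2 of 5 alternatives, where the log2 odds ratio of 4.48 ± 0.71 (SE) became 3.65 ± 0.84 with the list of replicate 1 alone (3 genes, adjusted exact p = 0.124) and 4.20 ± 0.97 over the 206 strongest peaks (2 genes, adjusted exact p = 0.272). The lin class was lost in 3 of 5, where the log2 odds ratio of 3.20 ± 0.66 became 2.905 ± 0.720 with the list of replicate 2 alone (4 genes, adjusted exact p = 0.172), 2.83 ± 0.66 with promoters from 2000 bp upstream (adjusted exact p = 0.067) and 2.56 ± 0.74 against genes with a relaxed peak (adjusted exact p = 0.20).

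The peak summits were rich in GAGA repeats and held no detectable excess of the hexamer chosen for sine oculis proteins. GAGAGA or its complement was within 50 bp of 26.5% of the 412 summits and in 4.61% of the windows 400 bp away (log2 ratio 2.49; exact McNemar test, two-sided, adjusted over 2080 hexamers, p = 1.0e-14). TGATAC, the core that sine oculis homeodomains recognise, was in 2.91% of summit windows and 2.67% of the others (12 and 11 peaks; log2 ratio 0.12, adjusted exact p = 1). The homeodomain core TAATTA was less frequent at summits, 2.18% against 7.28% (adjusted exact p = 0.0086), as was the GATA-type TGATAA, 2.91% against 9.22% (adjusted exact p = 0.0032). The TAATTA difference did not pass the threshold in the list of replicate 2 alone (log2 ratio -0.97 against -1.68 in the optimal list, adjusted exact p = 0.172) or over the 206 strongest peaks (-1.58, adjusted exact p = 0.114).

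Base composition differed between summits and flanks, which bears on every hexamer. GC content over the nuclear optimal peaks was 49.95% ± 8.27 (SD, n = 388) at summits and 36.8% ± 6.21 in the flanking windows, and 38.5% ± 11.5 at relaxed-only summits. In total 457 hexamers passed the threshold, 273 higher and 184 lower at summits. Among the higher ones were ACGCAG (15.05% against 1.94%) and CCTGCG (8.74% against 0.485%), and among the lower ones AAAAAA (13.3% against 39.8%). Within hexamers of the same base composition, GAGAGA ranked 1 of 20 by log2 ratio and TGATAC 14 of 102 (0.12 against a median of -0.66). TGATAA ranked 57 of 60 (-1.62 against a median of -0.81) and TAATTA 14 of 14 (-1.68 against a median of -1.31). With relaxed-only summits as control the ranks were 2 of 20, 20 of 102, 57 of 60 and 8 of 14, and TAATTA, at -1.51, was near the median of -1.45 for its composition. TGATAC, at 0.10, was above its median of -0.33 there. These ranks carry no test.

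**Figure D4:**
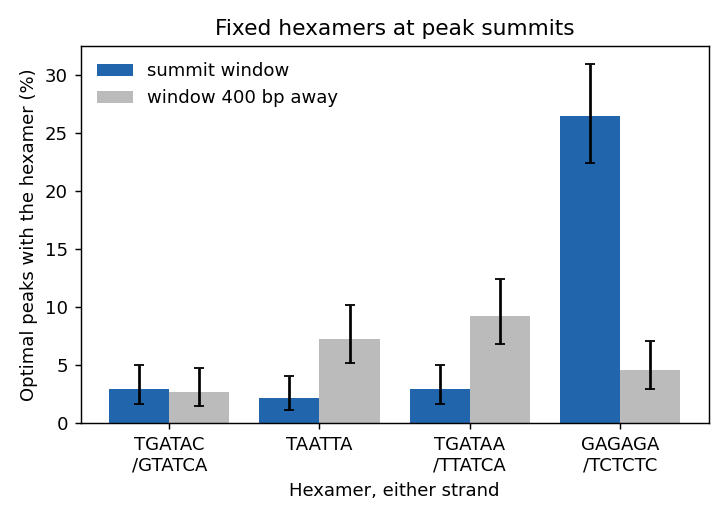
Share of the 412 optimal peaks with each fixed hexamer on either strand (y axis, percent) within 50 bp of the summit (blue) and in a window of equal width 400 bp away (grey), with Wilson 95% intervals. GAGAGA is in 26.5% against 4.61%, and TGATAC in 2.91% against 2.67%.

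The gene encoding the tagged protein had a dense cluster of peaks. Within 20 kb of the start of ceh-32 (WBGene00000453, V, 11701764 to 11705400, minus strand) there were 6 optimal peaks, and no nuclear protein-coding gene had more. The strongest, at 11704686 to 11704859, was in an intron of ceh-32, 634 bp downstream of its start, with a signal of 359 (223 in replicate 1 and 135 in replicate 2). The promoter peak at 11705471 to 11705890, 281 bp upstream, had a signal of 130 (52.1 and 74.6). A peak of signal 207 lay in an intron of the neighbouring trehalase gene tre-3, at 11711783 to 11712202. There were 20 relaxed pooled peaks within 20 kb, against a median of 3 over 19973 genes, and 25 and 16 in the lists of replicates 1 and 2. Within 20 kb of unc-119 there was no optimal peak and there were 6 relaxed ones, more than at 73.2% of genes. These counts describe the lists and carry no test, and reads from the ceh-32 sequence on the transgene map to the native gene.

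**Figure D5:**
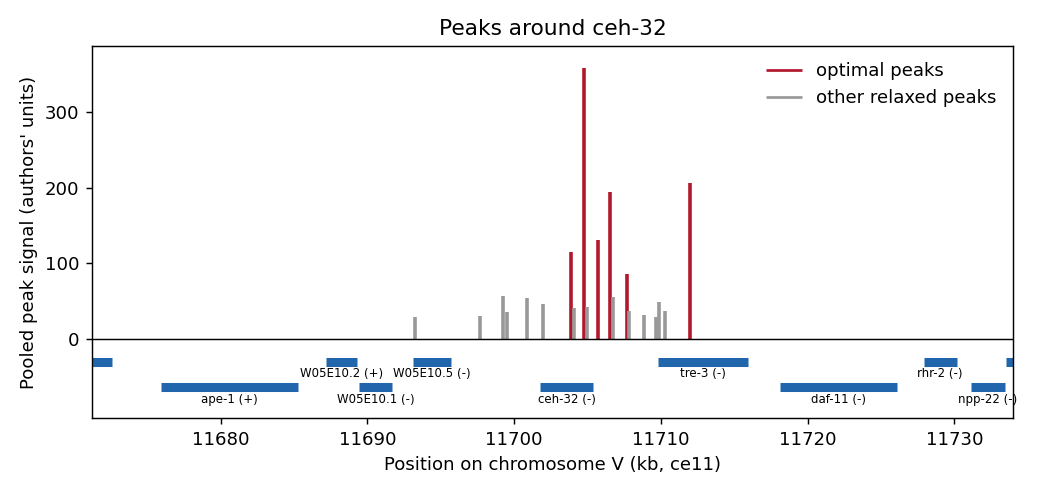
Pooled peaks around ceh-32 on chromosome V (x axis, position in kb on ce11; y axis, signal in the authors' units). Each line is a peak summit, red for the 6 optimal and grey for the 14 other relaxed peaks, some of which overlap an optimal one, and blue bars are protein-coding genes with their strand; the strongest peak, of signal 359, is inside ceh-32.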

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

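The tests of the mitochondrial peaks were chosen after the result was seen. The mitochondrial genome lies outside the comparisons of chromosomes and genes, yet 24 peaks of the optimal list were on it. They were flagged because they number more than 3, which is a rule for a closer look and not a test. Their median signal was 5378, which was 50.9 times the median of 106 at nuclear optimal peaks. Mitochondrial peaks were 22 of the 25 strongest in the relaxed list of replicate 1 and 23 of the 25 strongest in that of replicate 2. The optimal list was selected for reproducibility, so this recurrence follows from that selection. It is therefore no separate test of a library problem in a single replicate. The peak regions covered 86.7% of the mitochondrial genome, while no nuclear window of the same length was covered beyond 16.485%, so a candidate explanation is the high copy number of this genome. The control library was not analysed here and no biological explanation was tested, so how much of the signal goes beyond the copy number stays open.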

How the results depend on the processing

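Depth is unknown, so its effect on the number of peaks was not assessed. Settings without the mitochondrial peaks, without the peaks near ceh-32, and with X-linked or autosomal peaks alone were chosen after the data were examined. The number of optimal peaks was 435 on ce10, and 206 when the list was limited to its stronger part, by construction. The share of replicate 1 peaks found in replicate 2 went from 11.0% to 35.0% over 7 alternatives (distance, overlap, strength, build and no mitochondrial peaks), each above its circular shifts. Spearman's rho between replicates rose to 0.596 with summits within 50 bp (the cause was not tested). The promoter excess kept its direction and threshold in all alternatives except X-linked peaks alone (36.9%, exact p = 0.272), where the log2 odds ratio was 0.33 ± 0.28 (SE) against 1.38 ± 0.19 on the autosomes. The number of gene lists past the threshold was 2 against genes with a relaxed peak, and these were 2 of the 4 called in the main setting; there the log2 odds ratio went from -2.49 ± 0.78 (SE) to -0.87 ± 0.79 for chemoreceptor genes and from 3.66 ± 0.84 to 2.46 ± 0.92 for molting and heterochronic regulators. The ribosomal protein list and the translation factor and core chaperone list passed in all 9 alternatives, with adjusted exact p of at most 8.4e-05 in 8 of them and an adjusted permutation p of 0.0015, from the smallest p that 10000 draws can give, in the other. Against genes with a relaxed peak their log2 odds ratios fell from 4.15 ± 0.42 (SE) to 2.77 ± 0.46 and from 4.68 ± 0.50 to 3.91 ± 0.62. With linking by the nearest start within 5 kb their linked genes fell from 15 to 9 and from 11 to 7. The chemoreceptor list passed in 8. Pan-neuronal genes passed in the list of replicate 2 alone (5 of 42 linked, adjusted exact p = 0.0015), and Wnt, Notch, TGF-beta and EGF signalling genes when linked by the nearest start within 5 kb (6 of 63, adjusted exact p = 0.0034). The share of X kept its direction and threshold in all 5 alternatives, with 30.8% and 31.96% from single replicates. The prefixes rpl and rps passed in all 5 alternatives, hsp in 3 and lin in 2. TGATAC passed in none of 8 alternatives, with log2 ratios from -1.10 to 0.69, and GAGAGA in all 8. The number of hexamers past the threshold was 148 over the 206 strongest peaks and 210 with windows of 25 bp on each side. Relaxed peaks near unc-119 numbered 11 in replicate 2 and 13 within 50 kb.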

Other observations

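Small nuclear, small nucleolar and transfer RNA genes were frequent at the optimal summits. All tests in this part were chosen after the results were seen, except the comparison within 10 bins of GC content, for which the mean GC content of X-linked and autosomal optimal summits had been seen but not the result within bins. Of the 388 nuclear optimal peaks, 85 had their summit within 100 bp of a small nuclear, small nucleolar or transfer RNA gene, or 21.9%, against 2.84% of relaxed-only peaks (Fisher's exact test, two-sided, p = 9.6e-45). The share was 7.73% against 0.600% for small nucleolar RNA genes (30 peaks, adjusted exact p = 2.1e-20), 11.3% against 2.06% for transfer RNA genes (44 peaks, adjusted exact p = 1.0e-17) and 2.84% against 0.180% for small nuclear RNA genes (11 peaks, adjusted exact p = 8.1e-09). Together these classes were at 27.9% of X-linked optimal peaks (34 of 122) and 19.2% of autosomal ones (51 of 266; exact p = 0.064). All 34 on X were at transfer RNA genes, which had 44 peaks in all. The peaks at small nuclear and small nucleolar RNA genes were all autosomal. The pooled test thus joins classes that lie on different chromosomes, so it does not compare transfer RNA genes between X and autosomes. Genes of the unspecified ncRNA class, the largest but for piRNA genes, were within 100 bp of 25% of summits against 6.12% (97 peaks, adjusted exact p = 6.1e-30), and microRNA genes of 0.258% against 0.19% (adjusted exact p = 0.667). The small nuclear class in the annotation includes genes of the spliced leader RNAs that are joined to messages in operons. Several of the strongest autosomal peaks were at these genes, with sls-2.1 (signal 337 at II, 5844676 to 5844961) and sls-2.4 (signal 305 at I, 4172014 to 4172300, the peak that also lay in the promoter window of egg-5) first. Summits near piRNA genes were rarer than in the background, 0 of 388 (which allows up to 0.773%) against 2.00% (adjusted exact p = 0.0019).

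The excess of X-linked peaks, 31.4% of optimal against 20.1% of relaxed-only peaks, was weighed against sequence. The 8-mer GCGCAGGG, part of the motif known from the X-linked sites that recruit the dosage compensation complex, was within 100 bp of 9.84% of the optimal X summits (12 of 122), against 0.376% of the autosomal ones (1 of 266; Fisher's exact test, two-sided, p = 6.0e-06) and 0.298% of relaxed-only X summits (6 of 2012). Among the 25 strongest nuclear peaks it was in 8 of the 12 on X and in 0 of 13 on autosomes. GC content as the whole cause was argued against, since X-linked summits were not richer in GC (mean 49.37% ± 8.51 SD on X and 50.22% ± 8.15 on autosomes for optimal peaks, 38.11% ± 11.8 and 38.65% ± 11.5 for relaxed-only ones) and the log2 odds ratio of X was 0.90 ± 0.17 (SE) within 10 bins of GC content and 0.87 without them, and peaks with the exact 8-mer are not the whole excess, since 29.3% of the optimal peaks that lack it were on X against 20.1% (adjusted p = 1.7e-04). Dosage compensation sites caught in this immunoprecipitation may therefore account for part of the strongest X-linked peaks. Whether CEH-32 itself binds them stays open, and no biological explanation was tested. Summits within 100 bp of transfer RNA genes were a larger group on X, 34 of the 122 optimal peaks there. Of the 44 optimal peaks at such genes, 34 were thus on X. The 29.3% of X among peaks without the 8-mer still includes them. The part of these peaks in the X excess was not tested, so how much excess is left without both groups is not known.

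The cluster at ceh-32 was weighed against extra copies of the region on the transgene. Its 20 relaxed pooled peaks spanned 18757 bp, from 11693236 to 11711993 on V, and there were 0 relaxed peaks from 20 to 50 kb of the gene start, a gap that 3.97% of genes shared. The lists of replicates 1 and 2 had 6 and 2 peaks in that range, where the median over genes was 6 in the pooled list and 8 in each replicate, so an edge at which extra copies of the ceh-32 region end was not clear in both replicates. The strongest peak was 9.25 times the median of 38.8 over the 14 relaxed peaks of the cluster that are not in the optimal list, but copies raising every position alike leave such a ratio as it is, so these copies and binding of CEH-32 to its own gene cannot be told apart.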
